A study of Mus musculus with 32 samples.

How the data were processed

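Small-intestinal organoids of aged mice were treated with IFNγ at 500 pg/ml for 3 hours or with medium alone, per the labels' protocols. Fixed nuclei were digested with DpnII, ligated in situ, sonicated, indexed and captured by a low-input Capture-C protocol, per the labels. The submitters' processing notes name Bowtie2 and the build mm10; versions, the removal of duplicate reads and the settings of the contact caller are not given in the sources used here. The authors deposited 2 tables, each with 1 row per pair of a bait fragment and another fragment. Per the file headers, each table gives counts of reads in 4 columns, a merged value, a modelled background signal and a score per pair, in the layout of the CHiCAGO caller. The 4 columns are read as counts of 4 libraries: over pairs with 20 or more reads they differed 15.8 and 13.3 times more than counting error in the control-named and IFNγ-named table, which lanes of 1 library would not. The merged value is a rounded scaled mean and was treated as a score, as deposited. The score is the authors' own and was used only within its table, to call contacts.

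The columns do not name the mouse or passage, so libraries carry only a number within their table. The sample descriptions and the file names assign the tables to opposite conditions. No assignment was made from the values, and signed differences are given both ways.

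Fragment starts were checked against the GRCm38 sequence: 100% of 34744 starts lay at a GATC site when read as 1-based. Genes were named from the GENCODE annotation of the same build. Each bait, other fragment and count was joined between tables by fragment number, which gave 30435 pairs in one or both tables and 4358 in both. A pair listed in 1 table only was given counts of 0 in the other. Pairs between 2 baits are listed in both directions and were kept.

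Counts per pair were compared with edgeR 4.0.16 (quasi-likelihood test, TMM factors, pairs with 10 or more reads over both tables, Benjamini-Hochberg adjusted p of 0.05), with DESeq2 1.42.0 as an alternative, in R 4.3.3. In DESeq2, 359 adjusted p-values were NA and stayed so. Bait totals were compared by the same edgeR test. Shares per library were compared by two-sided exact permutation tests in scipy 1.17.1 under Python 3.11.15, where 4 against 4 libraries cannot give a p under 0.0286. Contacts were called at a score of 5 or more. A gene on a fixed list was reached where the other fragment lay within 1 kb of its TSS. All baited genes are named, a rule set before the data were examined, as were the gene lists, the edgeR tests and 118 of the 276 alternatives. The permutation tests of shares and the other 158 alternatives were chosen after seeing the data. The edgeR test was tested on simulated data with 200 changed features.

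The libraries held 23037 to 37290 reads, and 76.4% and 71.5% of the pairs in the control-named and IFNγ-named table had 1 read. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only. The carry-over level of a library was estimated from distant pairs with 40 or more reads of which 1 library held over 50%. A library was counted as above it with 3 or more reads and a binomial p under 0.01. Alternatives covered the score threshold, count filters, distance, pairs between baits, normalization, the test, the TSS window, libraries left out and the removal of the estimated carry-over.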

Results

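Chromatin contacts of 14 bait fragments were measured by Capture-C in small-intestinal organoids from aged C57BL/6JRj mice, with and without interferon gamma (IFNγ) at 500 pg/ml for 3 hours. Capture-C cuts crosslinked chromatin with a restriction enzyme, ligates fragments that lie close together and enriches the ligation products of chosen baits, whose reads are counted per pair of fragments. Organoids are epithelial cultures grown from intestinal stem cells. The 32 sequencing samples were 8 libraries run on 4 lanes each. Each condition had 4 libraries from 2 mice, with 2 passages per mouse, and both conditions came from the same mice and passages. The count columns do not name them, so the tests below treat the libraries as unpaired. All libraries were from aged mice, so no comparison of ages was possible. The libraries of the control-named table held 24549 to 37290 reads, 125363 in all, over 19286 fragment pairs. Those of the IFNγ-named table held 23037 to 30932 reads, 106017 in all, over 15507 pairs.

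Which table holds which condition is not settled. The sample descriptions attach the table named for the control to the IFNγ samples and the table named for IFNγ to the control samples. The tables are therefore called the control-named and the IFNγ-named table, and neither is assigned to a condition. Every signed difference is given as the IFNγ-named minus the control-named table, and its sign turns under the opposite subtraction. The 4 libraries of a table come from 2 mice, so p-values over libraries may be too small. Both conditions came from the same mice and passages, and leaving that matching unused may also make p-values too large.

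The baits lay at 12 genes. Ciita, the master regulator of MHC class II genes, had 3 baits on chromosome 16 (build mm10), at alternative start sites of the gene (ENSMUSG00000022504). Bait Ciita_1 spanned 10479663 to 10480580 and held 3 annotated transcription start sites (TSS). Bait Ciita_2 spanned 10486858 to 10489086 and held 2 TSS, and bait Ciita_3 spanned 10489551 to 10489878 and held 3. Stat3, a transcription factor of cytokine signalling, had its bait on chromosome 11 from 100938874 to 100939386. The other baits lay at Dppa5a, Esrrb, Klf2, Klf4, Lifr, Nanog, Phc1, Sall4, Sox2 and Tfcp2l1, most of them known from pluripotent stem cells. The Sox2 bait lay 126 bp and the Tfcp2l1 bait 182 bp from the nearest annotated TSS of the gene, and every other bait overlapped one.

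The first question was whether each bait's share of the captured reads differed between the tables. This share also depends on capture efficiency, so it is no measure of a gene's contact alone. The baits Ciita_2, Ciita_3 and Esrrb were the most deeply read in both tables. Ciita_1 took 6.06% ± 0.904 of the reads in the control-named table and 7.43% ± 0.756 in the IFNγ-named table (SD, n = 4 libraries each). Ciita_2 took 11.6% ± 1.10 and 12.4% ± 1.15, and Ciita_3 took 11.9% ± 1.503 and 12.2% ± 1.63. Stat3 took 6.30% ± 0.864 and 5.37% ± 0.707. The log2 difference of Ciita_1 was 0.31 (SE 0.145), or -0.31 with the sign turned, with an adjusted p of 0.490 by edgeR's quasi-likelihood test. The log2 difference of Stat3 was -0.22 (SE 0.147), or 0.22 with the sign turned, with an edgeR adjusted p of 0.675. None of the 14 baits passed an adjusted p of 0.05 in edgeR, and 1 of them, Ciita_1, had an unadjusted p under 0.05 (0.0350). Over all baits the log2 differences ran from -0.22 at Dppa5a to 0.31 at Ciita_1.

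**Figure D1:**
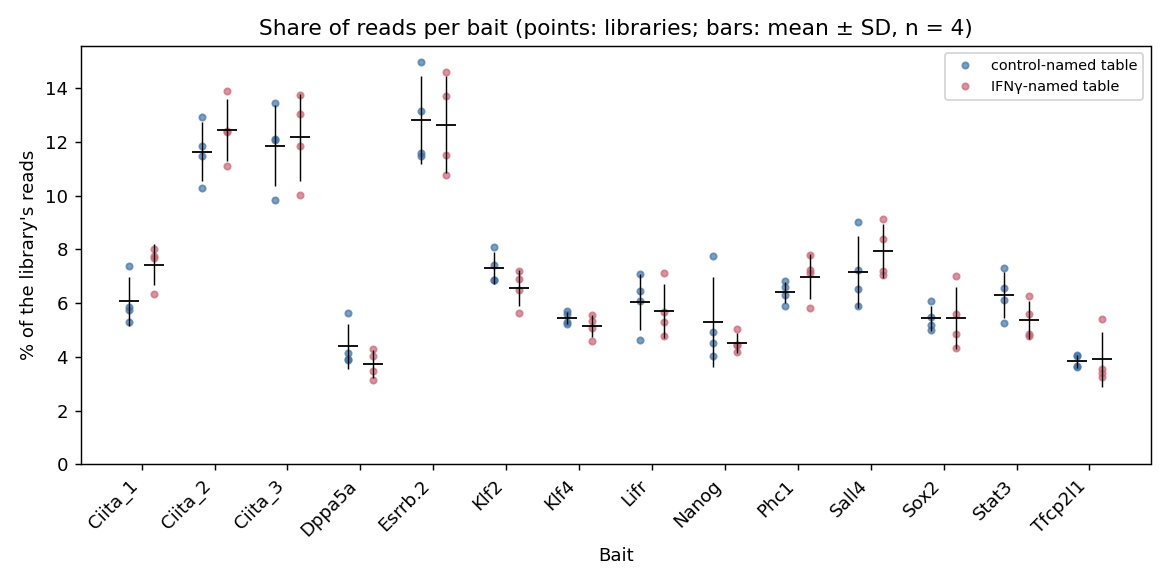
Share of each library's reads (y axis, percent) per bait (x axis) in the control-named (blue) and the IFNγ-named table (red). Points are libraries and bars are the mean ± SD of 4 libraries. Esrrb and 2 of the Ciita baits took over 10% of the reads in each table, and the libraries of both tables overlapped at every bait.

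Around Ciita, the reads of the 3 baits between 10 kb and 1 Mb fell most often, by mean share, on Ciita itself and on the neighbouring Dexi and Tvp23a in both tables. In the control-named table Clec16a came close to Tvp23a, and the order of these genes differed between libraries. The shares were corrected neither for distance from the baits nor for the number of fragments at a gene. Ciita, Dexi and Tvp23a also had the most fragment pairs with reads, 41, 36 and 25, against 1 to 18 at the other genes. The order is therefore no measure of a preference for these genes. Reads at Ciita made up 18.1% ± 2.03 of the 3 baits' reads in this range in the control-named table and 20.5% ± 5.01 in the IFNγ-named table (SD, n = 4 each). Dexi, which overlaps Ciita on the other strand and so shares fragments with it, held 15.6% ± 3.02 and 15.5% ± 3.19, a difference whose direction turned when single libraries were left out. Tvp23a, upstream of Ciita, held 7.71% ± 2.88 and 11.2% ± 4.5001. The share at Clec16a, downstream from 10545339 to 10744878, was 7.29% ± 1.71 in the control-named and 3.10% ± 1.14 in the IFNγ-named table. The share at Emp2, upstream from 10281749 to 10313968, was 3.30% ± 0.487 and 6.61% ± 2.82. For both genes the libraries of the tables did not overlap, which chance gives in 2.86% of genes. The gap at Emp2 was narrow: the lowest IFNγ-named library held 4.08% and the highest control-named library 3.87%. At Clec16a the highest IFNγ-named library held 4.74% and the lowest control-named library 5.88%. The shares rest on 7 fragment pairs at Emp2 and 18 at Clec16a. Each had a two-sided exact permutation p of 0.0286, the smallest that 4 against 4 libraries can give, and a Benjamini-Hochberg adjusted p of 0.171 over 12 genes. With 12 genes, 7 or more at that smallest p would be needed for any to pass an adjusted p of 0.05, so 2 could not pass. The remaining genes had exact permutation p-values of 0.114 to 0.943. These 12 genes were chosen for testing after the files had been examined.

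**Figure D2:**
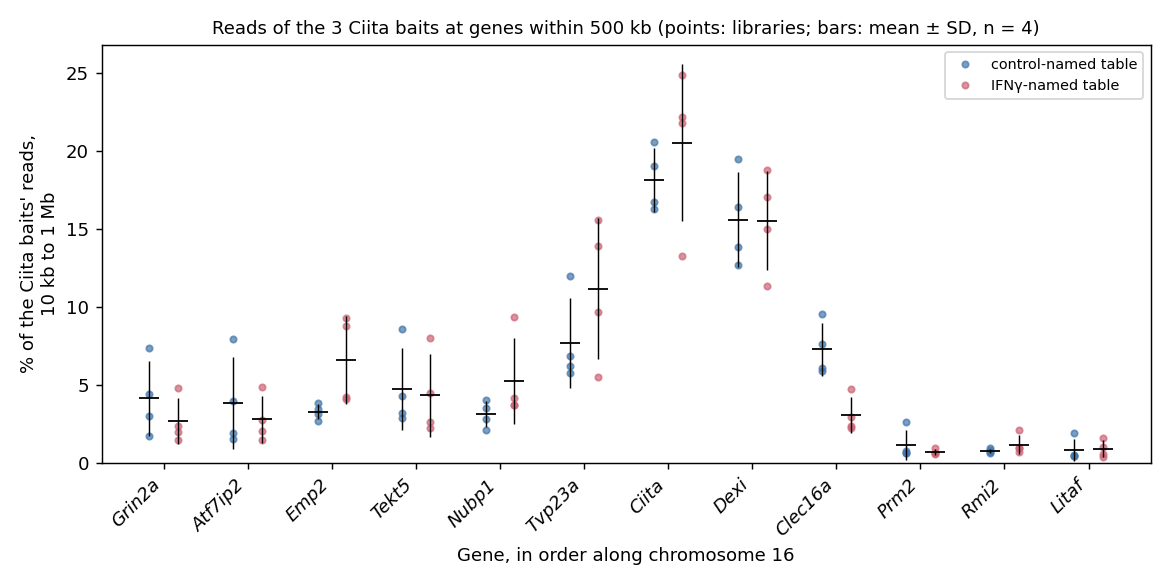
Percent of the reads of the 3 Ciita baits between 10 kb and 1 Mb (y axis) that fell within 2 kb of each protein-coding gene (x axis, in order along chromosome 16). Points are libraries, bars the mean ± SD of 4 libraries, blue the control-named and red the IFNγ-named table. The libraries of the tables did not overlap at Emp2 and Clec16a, with adjusted p of 0.171 for each by the exact permutation test.

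The overlap between the baits at the alternative Ciita start sites was counted over fragments they contacted. Among fragments with 10 or more reads between 10 kb and 1 Mb, Ciita_1 had 48, Ciita_2 had 85 and Ciita_3 had 68. Ciita_1 and Ciita_2 shared 8 of these fragments, where independent draws within 50 kb distance steps would share 3.5002. Ciita_1 and Ciita_3 shared 6, against 2.15, and Ciita_2 and Ciita_3 shared 8, against 4.36. The differences from these values were not tested. Ciita_2 had 73.2% ± 4.78 of its reads in this range upstream in the control-named and 67.6% ± 5.61 in the IFNγ-named table (n = 4 each; exact permutation p = 0.200). The upstream share of Ciita_1 was 47.2% ± 6.90 and 55.6% ± 14.07 (n = 4 each; exact permutation p = 0.343). The upstream share of Ciita_3 was 51.7% ± 7.77 and 55.1% ± 7.40 (n = 4 each; exact permutation p = 0.629).

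**Figure D3:**
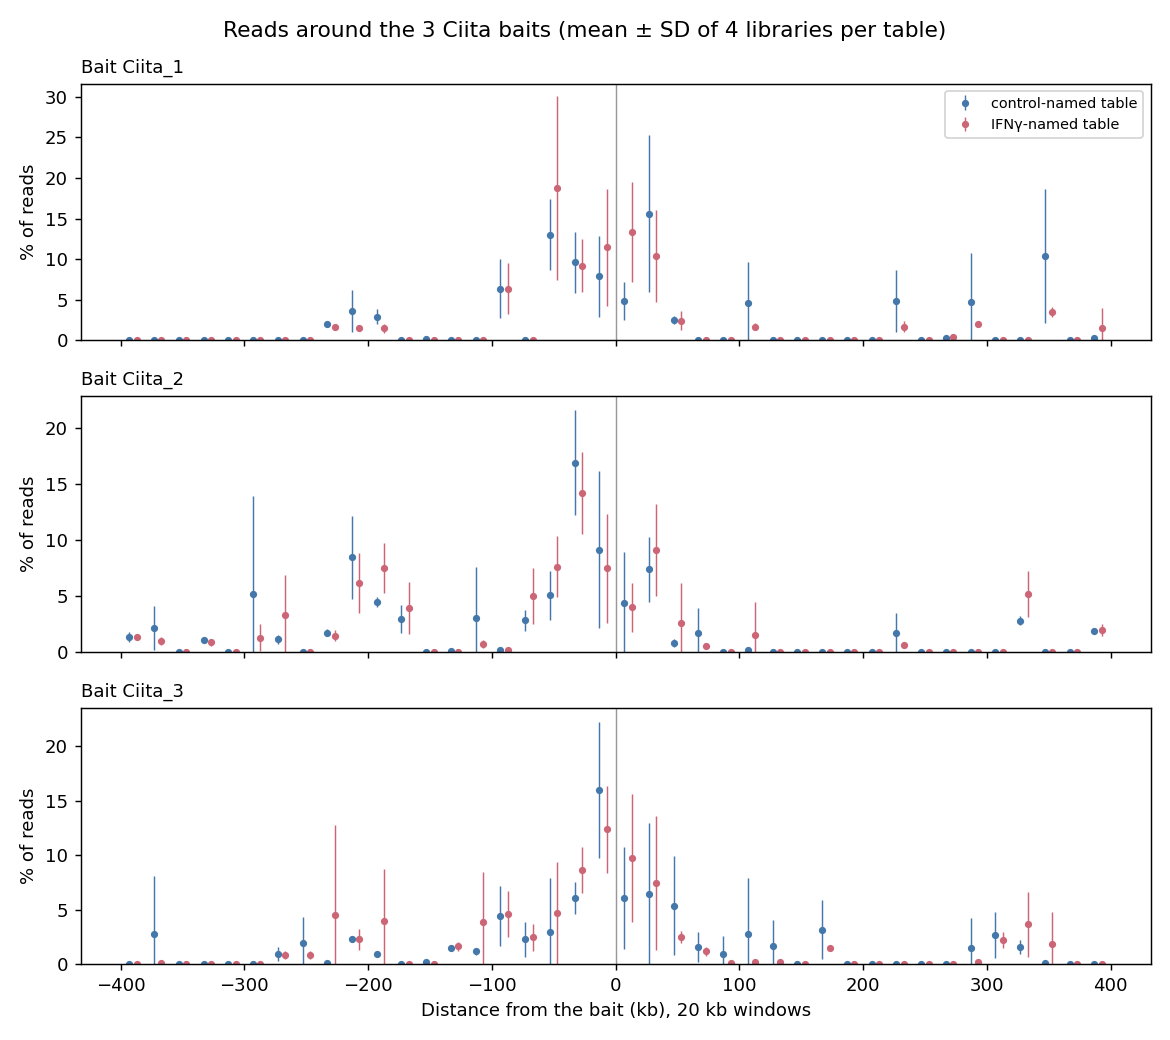
Percent of each Ciita bait's reads between 10 kb and 1 Mb (y axis) in 20 kb windows by distance from the bait (x axis, kb; negative is upstream). Points and bars are the mean ± SD of 4 libraries, blue for the control-named and red for the IFNγ-named table. In the control-named table the highest window of Ciita_2 began 40 kb upstream and held 16.9% ± 4.70 of its reads, against 14.2% ± 3.68 in the IFNγ-named table.

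Contacts were called where the authors' CHiCAGO score was 5 or more. The control-named table held 1323 called contacts and 1167 were called in the IFNγ-named table. With 2 or more libraries above the estimated carry-over level, a requirement added after seeing the data, these counts fell to 361 and 314. Of the 1811 pairs called in one or both tables, 1086 (60.0%) had 1 library above that level. The Ciita baits accounted for 304 and 296 of the called contacts, and Stat3 for 81 and 61. Esrrb had the most called contacts of any bait, with 153 and 133. Within 1 Mb, Ciita_3 had 14 and 12 called contacts, Ciita_2 had 9 and 8, and Ciita_1 had 7 and 6. No contact within 10 kb of a bait was called in either table. Contacts over 1 Mb away made up 47.3% of the calls in the control-named and 48.7% in the IFNγ-named table, and contacts with other chromosomes 42.2% and 40.9%. Beyond 1 Mb the merged values summed to 1139 and 1070 times the modelled background, and 100% of the pairs there lay above it. Only pairs with reads are listed, so fragments without reads are left out of these sums. The background there summed to 8.72 over 2151 pairs in the control-named and to 7.73 over 1902 in the IFNγ-named table. With so low a background a listed pair lies above it almost by selection, so these values do not measure how well the background was modelled. Of the pairs beyond 1 Mb, 29.1% in the control-named and 29.9% in the IFNγ-named table were called. What else entered the score is not given, so these values do not show which background those calls rest on. The scores were computed on the libraries of each table together, so these counts have no replicate error.

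The tables shared 679 called contacts, 37.5% of the 1811 called in one or both (Wilson 95% interval 35.3 to 39.7, counting error only). Independent lists drawn within each distance class, among the pairs with 10 or more reads, would share 541.7, and lists drawn over all 3673 such pairs 420.3. At 100 kb to 1 Mb 29 were shared, where independent lists would share 24.9. Beyond 1 Mb 324 were shared, against 282.6, and 326 joined other chromosomes, against 233.9. In 249 of the shared calls, no library of one table exceeded the estimated carry-over level, a limit set out in the closing section.

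The highest-scoring called contact of each bait within 1 Mb was named after its values were seen. For Ciita_2 it was a fragment at 10213243 to 10213829, 274.4 kb upstream, that overlapped an exon of Atf7ip2 and lay within 1 kb of a TSS of that gene, with scores of 4.39 in the control-named and 6.27 in the IFNγ-named table. For Ciita_1 and Ciita_3 it lay in an intron of Grin2a, a glutamate receptor subunit gene, at 699.3 kb and 727.2 kb upstream. In the control-named and IFNγ-named table the scores were 4.15 and 7.98 for Ciita_1 and 7.77 and 4.91 for Ciita_3. Each of these Ciita contacts was thus called in 1 table only. In the Ciita_1 contact 1 library held 58.7% of 150 reads, in the Ciita_2 contact 57.9% of 190 and in the Ciita_3 contact 59.5% of 195. The log2 difference was 2.01 (SE 0.798) for the Ciita_1 contact, 1.82 (SE 0.823) for Ciita_2 and -1.48 (SE 0.824) for Ciita_3, or -2.01, -1.82 and 1.48 with the sign turned. Their edgeR adjusted p-values were 0.284, 0.284 and 0.295. The contacts were picked by their scores, so the size and sign of these differences partly follow from that choice. For Stat3 the highest-scoring contact lay 837.3 kb from the bait, outside annotated genes, with scores of 7.33 and 4.12, and 1 library held 62.0% of its 121 reads.

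The main comparison asked which contacts differed between the tables. None of the 3673 fragment pairs with 10 or more reads passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, in either direction. By the unadjusted p, 608 pairs lay under 0.05 in edgeR, and the smallest adjusted p was 0.284. With the estimated carry-over removed, an alternative chosen after seeing the data, 315 of 3768 pairs lay under 0.05. DESeq2 also called 0 pairs, with 274 under an unadjusted p of 0.05. The biological coefficient of variation was 0.793 for fragment pairs, against 0.144 for bait totals. On counts simulated for this comparison, edgeR recovered 0 of 63 pairs changed by 2-fold, 0 of 67 changed by 4-fold and 1 of 65 changed by 8-fold, among 3530 pairs. Changes of up to 8-fold at a single fragment pair were thus mostly not recovered at this depth with the dispersion that edgeR estimated. The simulation spread the libraries around a common mean. In the data, 1 library held 48.8% of the reads on average in pairs with 40 or more reads, a shape that was not simulated. Recovery in the data may therefore differ from the rates given here for pairs and windows. In 10 kb windows within 1 Mb, 0 of 636 windows passed in edgeR, with 104 under an unadjusted p of 0.05. The simulation recovered 1 of 65 windows changed by 2-fold, 16 of 67 changed by 4-fold and 44 of 65 changed by 8-fold, among 618 windows. With the dispersion set to 0.02 at the same depth, it recovered 32 of 66 windows changed by 2-fold, 53 of 66 changed by 4-fold and 61 of 66 changed by 8-fold, among 629 windows. Of the simulated features, 421 of 618 and 431 of 629 windows were unchanged, against 3335 of 3530 pairs. Recovery after adjustment rises with the share of changed features, so the rates for windows and pairs are not comparable. Where few windows change, recovery would be lower than given here.

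The fixed gene lists met few called contacts. The list of MHC class II genes held 3 baits, all at Ciita, and the list of interferon signalling held 1, Stat3. The remaining 6 lists had no bait. Of the class I genes, H2-Q2 had 1 called contact at its TSS, from the Esrrb bait on another chromosome, in the control-named table alone, and 1 library held 57.1% of its 21 reads. No called contact in either table reached a TSS of a gene on the class II, interferon signalling, interferon-induced effector, intestinal stem cell, differentiated epithelium, other cell type or housekeeping lists. No contact was called as changed, so Fisher's exact test inside against outside a list had nothing to compare.

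The distance profile of the reads was close to equal in the tables. Reads within 10 kb of a bait made up 8.97% ± 1.46 in the control-named and 8.73% ± 0.449 in the IFNγ-named table (SD, n = 4 each). Reads at 10 to 100 kb made up 12.04% ± 0.996 and 12.4% ± 0.998, and reads at 100 kb to 1 Mb 13.96% ± 0.526 and 13.3% ± 1.18. Reads beyond 1 Mb made up 29.1% ± 1.26 and 29.2% ± 1.01, and reads on other chromosomes 35.9% ± 2.62 and 36.4% ± 1.57. The two-sided exact permutation p-values of the 5 classes ran from 0.343 to 0.971, and each adjusted p was 0.971.

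**Figure D4:**
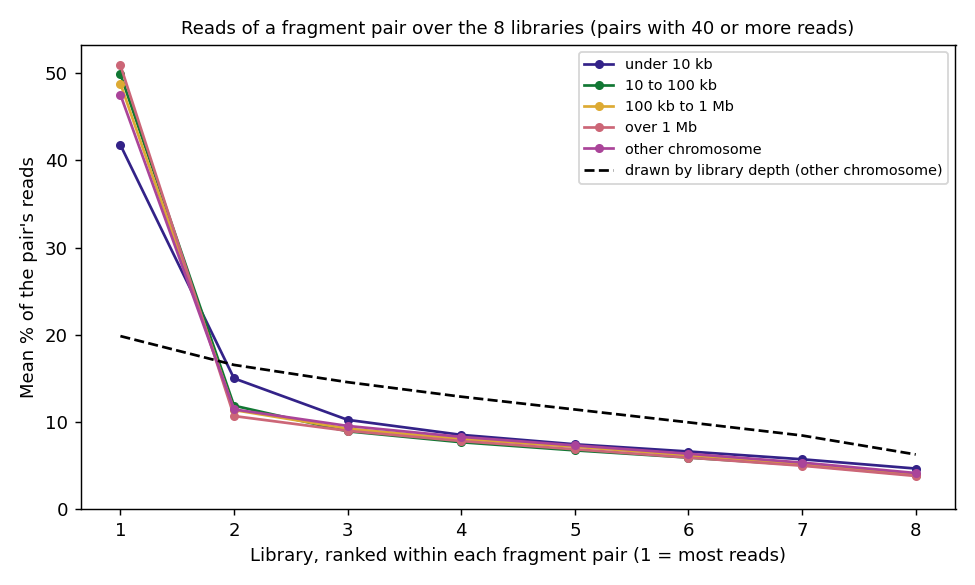
Mean percent of a fragment pair's reads (y axis) in each of the 8 libraries, ranked within the pair from most to fewest reads (x axis), by distance class, for pairs with 40 or more reads. The dashed line gives the shares drawn from library depth alone. The top library held 47.5% of the reads of pairs on other chromosomes, against 19.8% by depth.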

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

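The tests of carry-over and of the background near the baits were chosen after the pattern was seen, except the test of the reads in the other libraries by step of the top count. Of 64 groups of 4 libraries, 6 had a library far from the other 3, where chance gives about 3.20. Dppa5a took 5.64% of the reads in library 3 of the control-named table, against 3.89% to 4.15% in the others. Tfcp2l1 took 5.42% in library 2 of the IFNγ-named table, against 3.27% to 3.53%. Of the Ciita baits' reads between 10 kb and 1 Mb, Prm2, with 1 fragment pair, held 2.62% in library 2 of the control-named table, against 0.621% to 0.804%. Prm2 held 0.994% in library 3 of the IFNγ-named table, against 0.614% to 0.655%. Litaf held 1.90% in library 1 of the control-named table, against 0.452% to 0.509%, and Nubp1 held 9.35% in library 2 of the IFNγ-named table, against 3.69% to 4.19%.

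In fragment pairs with 40 or more reads, 1 library held 48.8% of the reads on average and the second 11.5%, and 1841 of these 1867 pairs were found in all 8 libraries. In 42.3139% of these pairs 1 library held over 50% of the reads, and 0 pairs did when reads were drawn by depth. That draw treats reads as independent molecules, which they are not, so a contact formed alike in every culture, or a mapping error, stays open. Separately amplified products in each library are argued against, because in the 404 pairs with over 50% in 1 library and 20 or more reads outside the top library, the counts of the other 7 spread 0.8547 times counting error, against 4.06 to 5.57 times in 200 shuffles of each library over pairs of the same distance class, selected the same way. Reads carried over between pooled libraries may account for it as a hypothesis: a library of the same table held 1.0022 times the share of a library of the other table (4.58% and 4.57%). A level alike in all libraries would give the same ratio, so it does not tell carry-over from the explanations left open. Carry-over of a fixed share alone would also make reads in the other 7 libraries rise as steeply as the top count. A contact at a steady level in all cultures that 1 library over-amplified stays open too: in pairs with other chromosomes and a top count of 5 or more, whatever their total, reads in the other 7 rose 4.3929-fold over the steps of the top count, less than the 12.7-fold rise of the top count itself, and a level that differs between pairs would also give a rise.

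No contact within 10 kb of a bait was called. Too few reads there are not excluded. Of the pairs under 10 kb, 37.0518% in the control-named and 38.6% in the IFNγ-named table had as many reads as the median called contact beyond 1 Mb (38 and 34 reads). That cannot decide the question, because the modelled background differed between these distances. In the control-named table it summed to 33836 over 251 pairs under 10 kb and to 8.72 over 2151 pairs beyond 1 Mb. In the IFNγ-named table it summed to 17998 over 251 and 7.73 over 1902 pairs, so a call near a bait needs more reads. The modelled background may be the cause: at most 19.9203% of the pairs under 10 kb had a merged value above it, and the merged values summed to 0.0898 of the background in the control-named and 0.134 in the IFNγ-named table, with a median of 0.218 and 0.303 over pairs. Fewer reads there than the model assumed would give the same ratios, so these explanations cannot be told apart. No biological explanation was tested for either pattern.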

How the results depend on the processing

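No paired analysis was possible because the columns of the tables do not name the mouse or passage of a library, although both conditions came from the same ones; the planned test for pooled counts was not run because the tables hold libraries. The alternatives with 10 kb windows, distance limits for changed contacts, pairs between baits for changed contacts, no TMM, carry-over and libraries left out of the shares were chosen after seeing the data; the test by splits below was set before its result was seen. The count of 0 changed contacts stayed 0 in edgeR with DESeq2's size factors, no TMM, filters of 5 or 20 reads, called pairs, windows, pairs within 1 Mb, pairs between baits left out, the estimated carry-over removed and each library left out (377 to 483 pairs at an unadjusted p under 0.05, and 315 with the estimated carry-over removed), and in DESeq2. Without a filter on low counts edgeR called 168 pairs, 77 higher and 91 lower in the IFNγ-named table (the reverse with the sign turned); all 168 had 10 or more reads and over 50% of them in 1 library. As many were called in 10 of the 35 splits of the 8 libraries, with up to 177 in another split, so chance is not excluded. Bait totals had 0 calls throughout, with a smallest adjusted p of 0.0702 to 0.8292 over the libraries left out in turn.

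Called contacts came to 2341 in the control-named and 2109 in the IFNγ-named table at a score of 3, to 765 and 690 without other chromosomes, and to 361 and 314 with 2 or more libraries above the carry-over level. At a score of 10 they came to 935 and 787, within 1.5 times the counts at a score of 5. Shared calls came to 958 (52.9%, outside the interval of the reported share) where a score of 3 was enough in one table, to 438 at a score of 10, 1561 at a score of 3 and 430 with a library above the carry-over level in each table. At a score of 3, the share of calls under 10 kb was 4.61% and 4.17%, at 10 to 100 kb 17.9% and 18.7%, at 100 kb to 1 Mb 20.8% and 21.2%, beyond 1 Mb 32.8% and 33.2% and on other chromosomes 23.8% and 22.6%, in the control-named and IFNγ-named table. At a score of 10 it was 0% at 10 to 100 kb and 0% at 100 kb to 1 Mb in each, and 50.9% and 50.3% on other chromosomes. At a score of 3, class II genes had 7 and 5 contacts at a TSS and interferon signalling genes 3 and 2. All lay on the bait's chromosome and may be at Ciita and Stat3 themselves. The 5 kb TSS window gave interferon signalling genes 2 and 1, and class II and housekeeping genes 1 each in the IFNγ-named table. The class I contact was lost at a score of 10 (0). The cause of these shifts was not tested. With 1 library left out in turn, the difference in share between the tables (IFNγ-named minus control-named, in percentage points; signs turn under the opposite subtraction) changed direction at 5 of the 12 genes around Ciita. It ran from -1.84 to 0.316 at Atf7ip2, -1.63 to 0.880 at Tekt5, -1.14 to 1.33 at Dexi, -0.622 to 0.0432 at Prm2 and -0.149 to 0.441 at Litaf, and was 0.307 at Dexi with the estimated carry-over removed. Of the other alternative values, 121 kept their direction and side of the threshold (in 83 of them, shares with 1 library left out, an exact permutation p under 0.0571 was not possible), 52 counts stayed within 1.5 times the reported count, 50 shares of reads moved by less than 1 SD and 4 shares of calls stayed within their interval.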

Other observations

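The test for promoters was set before its result was seen, and the comparison of calls on neighbouring fragments was planned before the data were examined. The other tests here were chosen afterwards. With the estimated carry-over removed, the share of the Ciita baits' reads at Clec16a was 8.26% ± 2.24 in the control-named and 2.16% ± 1.59 in the IFNγ-named table, and at Emp2 2.38% ± 0.706 and 7.40% ± 4.41 (SD, n = 4 each). The exact permutation p of each was 0.0286 before and after, the smallest possible, so it cannot show whether the difference grew or shrank. Clec16a lies downstream and Emp2 upstream of Ciita. The adjusted p of 0.171 over 12 genes follows from that limit, and the direction by condition is open.

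Fragments contacted between 10 kb and 1 Mb were tested for the hypothesis that promoters of other genes are contacted more often than other fragments. Of 1052 contacted fragments, 8.17% lay within 1 kb of a protein-coding TSS. Fragments matched for bait, length and distance had 7.49% ± 0.753 (SD of 1000 draws), a difference of 0.686 percentage points, and 188 of the draws were as high (permutation p = 0.189). An excess at promoters was not detected, and a small one is not excluded. No called contact of the control-named table had a called contact on the next fragment in the IFNγ-named table, on either side. Of the 54077 fragments between 10 kb and 1 Mb of a bait, 2.29% held reads, so neighbouring calls would be rare in any case.

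The number of pairs with an unadjusted p under 0.05 does not set the tables apart. As many as the 608 of the real grouping occurred in 3 of the 35 splits of the 8 libraries, with 640 as the highest other, so chance is not excluded. For bait totals, 15 of the 35 splits had as many baits at an unadjusted p under 0.05 as the real 1, with 3 as the highest other.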
